A study of Homo sapiens with 15 samples.

How the data were processed

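Muscle biopsies taken at below-knee amputation were profiled by bulk RNA sequencing, with Trizol and RNeasy extraction and single reads of 50 bases on a HiSeq-3000 per the labels' protocols. The deposited table holds counts, whole numbers of reads per gene name for 15 libraries, which the authors made with STAR 2.5.4b and Subread on hg38 per the submitters' processing notes. The table also gives a length in bases for each gene name, which was used only for the length correction. The annotation release and the strand of the libraries are not given in the sources used here, so reads of overlapping antisense genes and of close paralogs (HBA1 and HBA2, MYH6 and MYH7, HSPA1A and HSPA1B, TPSAB1 and TPSB2) were not assigned with certainty. Coordinates are those of GENCODE release 29 (GRCh38, the same build as hg38), in which 54302 of 56100 gene names had exactly 1 gene.

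Groups followed the group designation in the labels: MNC MG (n = 4), DPN MG (n = 4), MNC AH (n = 3), DPN AH (n = 2) and DPN (sev) AH (n = 2). For 1 library, DPN AH replicate 1, the source name and tissue fields give the calf muscle while title, description and group designation give the foot muscle, and it was kept in DPN AH. The labels carry "sev" only for foot muscle, and the calf libraries of the same 2 donors are labelled DPN. Both fits counted libraries as the unit, and 6 of 9 donors gave 2 libraries, 1 per muscle. No donor stands on both sides of a comparison between diagnoses.

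The table held 56609 gene names. Genes of chromosome Y, XIST and TSIX (509) were left out before any test to protect the donors. A check for mixed-up samples on those genes found 0 of 6 donor pairs that did not match. It cannot see swaps between donors of the same sex or between the muscles of a donor. Total counts were 8044427 and 8866319 in DPN (sev) AH, 8177833 and 11326662 in DPN AH, 9582074, 32066908, 10009976 and 10746544 in DPN MG, 11818133, 13710970 and 10461023 in MNC AH, and 9826166, 13248117, 11009211 and 11248160 in MNC MG. TTN took the largest share of counts in each library, 9.83 to 21.97 percent. Mitochondrially encoded RNAs took 10.81 and 10.82 percent in DPN (sev) AH and 13.62 to 42.58 percent elsewhere. At these depths a gene at 1 CPM has about 10 counts in most libraries, so genes under 1 CPM carry little information. Between libraries of the same group, which come from different donors, the chi-square per gene against counting noise was 28.7 to 244.9.

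Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr on the 5 groups (minimum count 10, minimum total 15), which left 20060. Scaling factors were TMM (trimmed mean of M values), 1.87 in both DPN (sev) AH libraries, 1.21 and 1.33 in DPN AH, 1.23, 0.80, 0.84 and 1.10 in DPN MG, 0.80, 0.63 and 0.97 in MNC AH, and 0.74, 0.67, 0.83 and 0.96 in MNC MG. CPM values use effective library sizes, the counts in the tested genes times the scaling factor. Quasi-likelihood F tests (robust) were fitted to all 15 libraries, in 5 groups for comparisons of the labelled groups, and in 4 groups with DPN AH and DPN (sev) AH together for the pooled, muscle and interaction comparisons. P values were adjusted with Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors of log2 folds are standard errors derived from the F statistic. The comparisons, tests, named-gene rule and 34 gene lists (12 of them cell types) were chosen before the data were examined.

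Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with camera's estimated correlation and with fry. Camera's preset assumes nearly independent genes, and with the estimated correlation 0 lists passed in any comparison, so list calls rest on that setting. Fry asks another question, whether a list differs from no change. A list's score in a library is the mean log2 CPM of its members (prior count 2) minus their mean in MNC MG. Named genes were the 10 higher and 10 lower with the smallest adjusted p among those past the threshold, with a log2 fold of at least 1 in size, a mean CPM of at least 1 and no overlap between groups (the first 5 in the smaller comparisons and the interaction). Where fewer than 5 passed in a direction, the first 5 by unadjusted p were eligible, and from each list up to 4 members with the smallest p. The text names a part of those. Clone names, noncoding and pseudogene names and genes that can show a donor's genotype were passed over. PTGFR in foot muscle was named outside the rule, after its values were seen. A fold against a group of zeros is given as a lower bound against a floor of 3 counts over that group's libraries.

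The alternatives fixed at the start were DESeq2, DESeq2 size factors in edgeR, limma-voom, limma-voom with the donor as a random block, the donor as a fixed block (muscle comparisons and interaction, donors with both muscles only), no filter, a fit with only the libraries compared, and leaving out each library. Library totals without scaling factors, list counts under leave-one-out and with the fixed donor block, a length and GC content correction, and splits with all 15 libraries in the fit were added after the data had been seen. The donor correlation in limma-voom was 0.393 with 5 groups and 0.37 with 4, so the 2 muscles of a donor were treated as pairs in those fits. Pairing was uneven, and those fits use a common value for all donors. Over log2 CPM relative to the group mean, the 2 muscles correlated at 0.16 and 0.18 in the donors of DPN (sev) AH. The other donors with both muscles had 0.41 to 0.47. Where a fit left a group with 1 library, that library was assumed to vary like the others. The length and GC correction removed each library's loess trend from log2 CPM for 19682 genes with both values (98.1 percent). Splits of the libraries into other groups of the same sizes were counted in full, 35 per comparison.

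The pipeline was tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold among 20060 genes. Recovery of 2-fold and 4-fold changes was 4 and 65 percent for DPN MG against MNC MG, 4 and 54 for pooled foot muscle, 1 and 21 for DPN (sev) AH against MNC AH, and 1 and 51 between control muscles, with 0, 2, 2 and 3 unchanged genes called. The sign was right for all changes of 4-fold. Changes of 2-fold were therefore mostly out of reach in the simulation. It drew all libraries independently, with no shared donors and few changed genes. Its rates of recovery and of false calls therefore need not hold in the real libraries.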

Results

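RNA from 2 skeletal muscles of people undergoing below-knee amputation was sequenced in 15 libraries from 9 donors, 6 of whom gave both muscles. The medial gastrocnemius (MG, calf) came from metabolically normal controls (MNC MG, n = 4) and from donors with diabetic peripheral neuropathy (DPN MG, n = 4). The abductor hallucis (AH, foot) came from controls (MNC AH, n = 3) and from donors with neuropathy in 2 groups, DPN AH (n = 2) and DPN (sev) AH (n = 2). The labels do not spell out "sev". No group had diabetes without neuropathy, so diabetes and neuropathy cannot be told apart in any comparison between diagnoses. Libraries held 8044427 to 32066908 counts. In all, 20060 genes were tested with edgeR quasi-likelihood (QL) tests and Benjamini-Hochberg adjustment at 0.05. Groups of gene lists fixed beforehand were tested with camera, and expression is given as CPM, the usual share of a library's counts after TMM scaling.

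**Figure D1:**
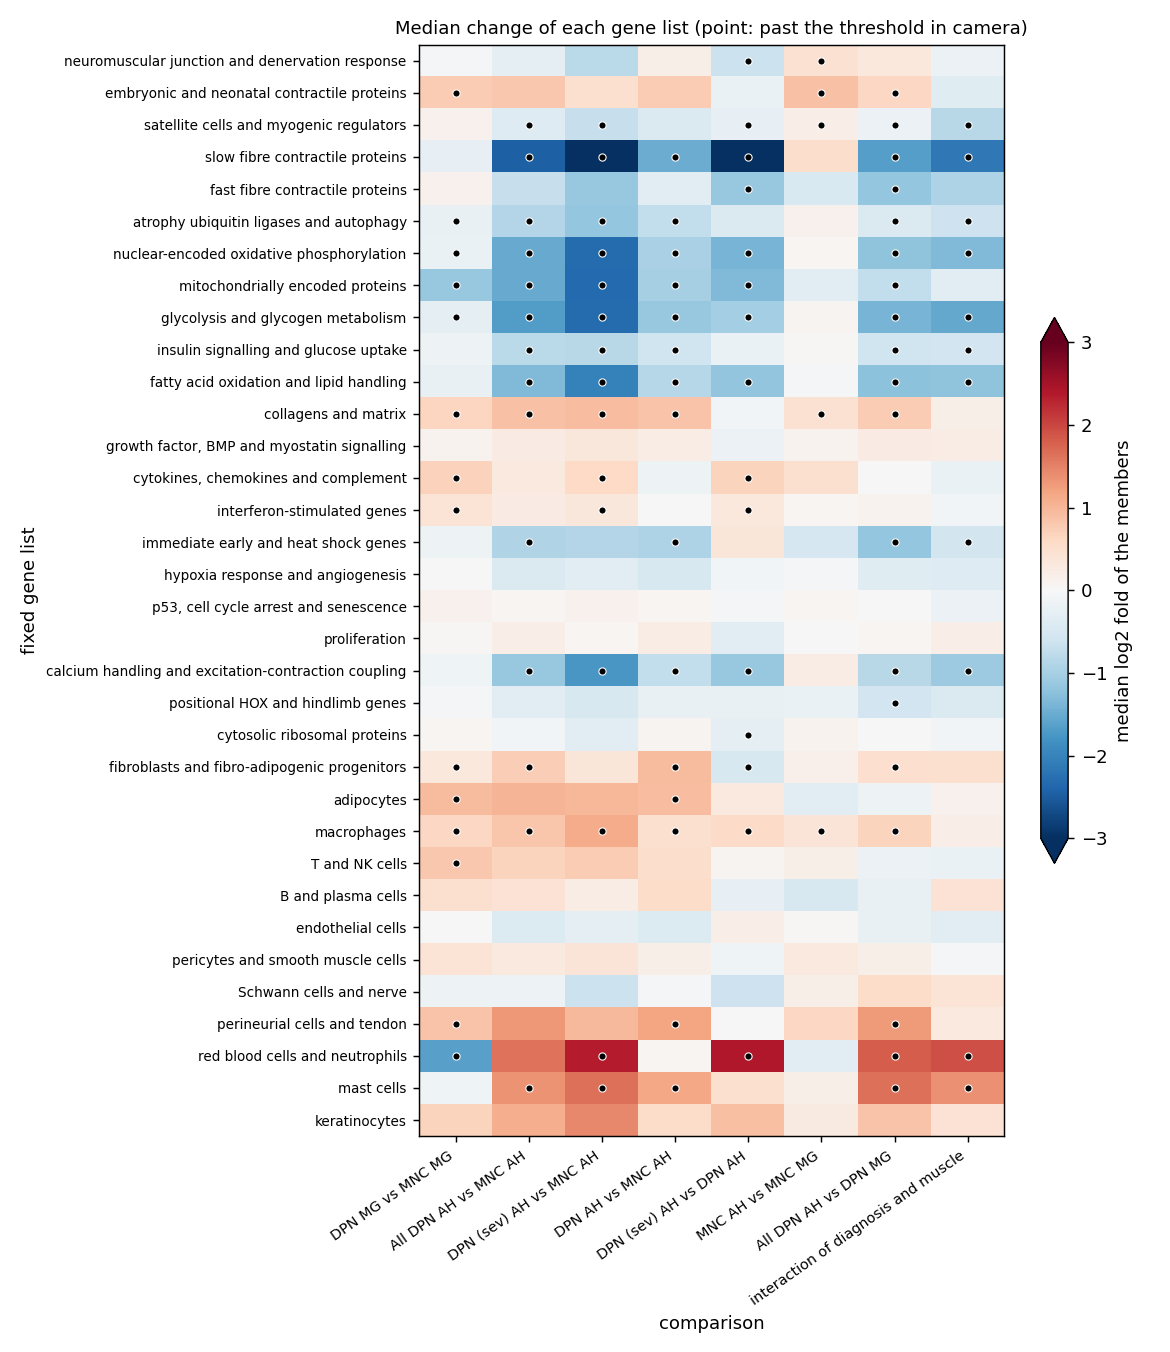
Median log2 fold of the members of each of 34 fixed gene lists (vertical) in each of 8 comparisons (horizontal), colour from -3 to 3, with a point where camera with its preset correlation put the list past the threshold. Slow fibre contractile RNAs had the lowest median, -5.61, in DPN (sev) AH against MNC AH.

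The first question was whether calf muscle differed between donors with neuropathy and controls (DPN MG against MNC MG, 4 libraries each). PTGFR, the receptor for prostaglandin F2alpha that acts on muscle growth and fibroblast activity, was the 1 gene past the threshold and was higher (ENSG00000122420.9, hg38 chromosome 1, 78303884 to 78539749). It averaged 21.1 ± 4.92 CPM (SD, n = 4) in DPN MG and 3.66 ± 1.18 CPM (SD, n = 4) in MNC MG, 5.73-fold. The log2 fold was 2.52 ± 0.34 (standard error), with an adjusted p of 0.032 in edgeR QL with Benjamini-Hochberg, and it did not pass in limma-voom with the donor as a random block (adjusted p = 0.085). Genes next in line did not pass: KAZN, a desmosome-associated protein (log2 fold 1.78 ± 0.31, adjusted p = 0.31), BMPER, a BMP-binding regulator (1.48 ± 0.28, adjusted p = 0.43), and HP, haptoglobin (2.11 ± 0.40, adjusted p = 0.43), all higher in every DPN MG library. On the lower side, the sodium-calcium exchanger gene SLC8A3 (-0.85 ± 0.24) and the sodium channel gene SCN7A (-1.53 ± 0.47) did not pass either, both with an adjusted p of 1.

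Camera called 14 of the 34 lists in calf muscle, 9 higher and 5 lower, although 0 of their members passed on their own genome-wide. All 13 mitochondrially encoded protein genes were lower, MT-CO2 and MT-ND4L among them (list median -1.13, camera adjusted p = 1.4e-14, and adjusted p = 0.57 with an estimated correlation). Collagens and matrix genes leaned the other way, 35 of 36 positive (median 0.65, adjusted p = 1.7e-09, and adjusted p = 0.58 with an estimated correlation), with VCAN at 1.48 ± 0.42, COL12A1 at 1.11 ± 0.46 and LOX at 0.94 ± 0.40. All 17 macrophage genes were positive (median 0.61, adjusted p = 6.8e-08, and adjusted p = 0.57 with an estimated correlation), including the scavenger receptor CD163 (1.22 ± 0.41) and the mannose receptor MRC1 (0.67 ± 0.32). Interferon-stimulated genes (median 0.41, adjusted p = 9e-06) and cytokines, chemokines and complement (median 0.69, adjusted p = 6.2e-05) were also higher, each with an adjusted p of 0.57 with an estimated correlation. Adipocyte genes, PPARG among them, had a median of 0.94 (adjusted p = 0.00083), perineurial and tendon genes 0.85 (0.018) and embryonic and neonatal contractile proteins 0.77 (0.025), each with an adjusted p of 0.58 with an estimated correlation. COMP, a cartilage matrix protein of the perineurial and tendon list (4.23 ± 1.15), passed only when adjusted over the list alone. CLDN1, a tight junction protein of the same list, also passed over the list alone, but lower (-3.43 ± 1.12, from 5.60 ± 7.25 to 0.412 ± 0.711 CPM, SD, n = 4 each). SLC2A1 of that list was negative too (-1.5 ± 0.91), while THBS4 (1.39 ± 0.82) and SCX (0.85 ± 0.40) were positive. The list mixes 2 tissues, and its call does not show that both were higher. T and NK cell genes (median 0.81, adjusted p = 0.024, and adjusted p = 0.64 with an estimated correlation) and fibroblast genes (0.32, 0.024, and adjusted p = 0.69 with an estimated correlation) completed the higher lists. The lower ones were nuclear-encoded oxidative phosphorylation (-0.20, 0.00071, and adjusted p = 0.69 with an estimated correlation), glycolysis (-0.29, 0.013, and adjusted p = 0.64 with an estimated correlation), and atrophy ubiquitin ligases and autophagy with TRIM63 (-0.22, 0.037, and adjusted p = 0.58 with an estimated correlation). Red blood cell and neutrophil genes were lower too (-1.64, 0.014, and adjusted p = 0.64 with an estimated correlation). Only 5 of the 14 calls held in each of the 8 fits without 1 library, those of the mitochondrially encoded, collagen, macrophage, interferon-stimulated and cytokine lists. Fry called no list in calf muscle, and the scores of these 5 lists overlapped between DPN MG and MNC MG. Collagen scores were -0.22 to 1.44 against -1.03 to 1.09, macrophage scores 0.36 to 0.97 against -0.86 to 0.82. Mitochondrially encoded scores were -1.63 to -0.46 against -0.76 to 0.97. The oxidative phosphorylation and glycolysis calls rested largely on DPN MG replicate 1, with scores of -1.02 and -1.32 against -0.19 to 0.27 and -0.24 to 0.26 in the other 3 DPN MG libraries. Without it their adjusted p was 0.82 and 0.79, and without MNC MG replicate 1 it was 0.35 and 0.36. The atrophy call was lost without DPN MG replicate 1 (0.063), DPN MG replicate 2 (0.12) or MNC MG replicate 2 (0.65), and the adipocyte call without DPN MG replicate 4 (0.51). The blood call was lost without DPN MG replicate 2 (0.11), MNC MG replicate 1 (0.065) or MNC MG replicate 2 (0.3). The embryonic, fibroblast, perineurial and T and NK cell calls were each lost in 5 of the 8 fits, with adjusted p reaching 0.26 (without DPN MG replicate 4), 0.45 (MNC MG replicate 3), 0.22 (MNC MG replicate 1) and 0.78 (DPN MG replicate 4). The medians of the oxidative phosphorylation and atrophy lists became 0.03 and 0.13 without scaling factors, and the atrophy list was not called (adjusted p = 0.12). Of the denervation response genes, the neural adhesion molecule NCAM1 (1.00 ± 0.45) and the synaptic kinase MUSK (1.55 ± 0.73) did not pass, and their list was not called.

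The calf count depended on tool, filter and library. At an unadjusted p under 0.05 there were 677 genes, 3.4 percent of those tested, a share below what no difference at all would give on average. DESeq2 called 8, limma-voom 0 and edgeR QL without a filter on low counts 273, PTGFR among them. PTGFR stayed past the threshold in 2 of 8 fits that left out 1 library, those without DPN MG replicate 4 or MNC MG replicate 3. The count was 0 in the other 6 (without DPN MG replicate 1, 2 or 3, or MNC MG replicate 1, 2 or 4).

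**Figure D2:**
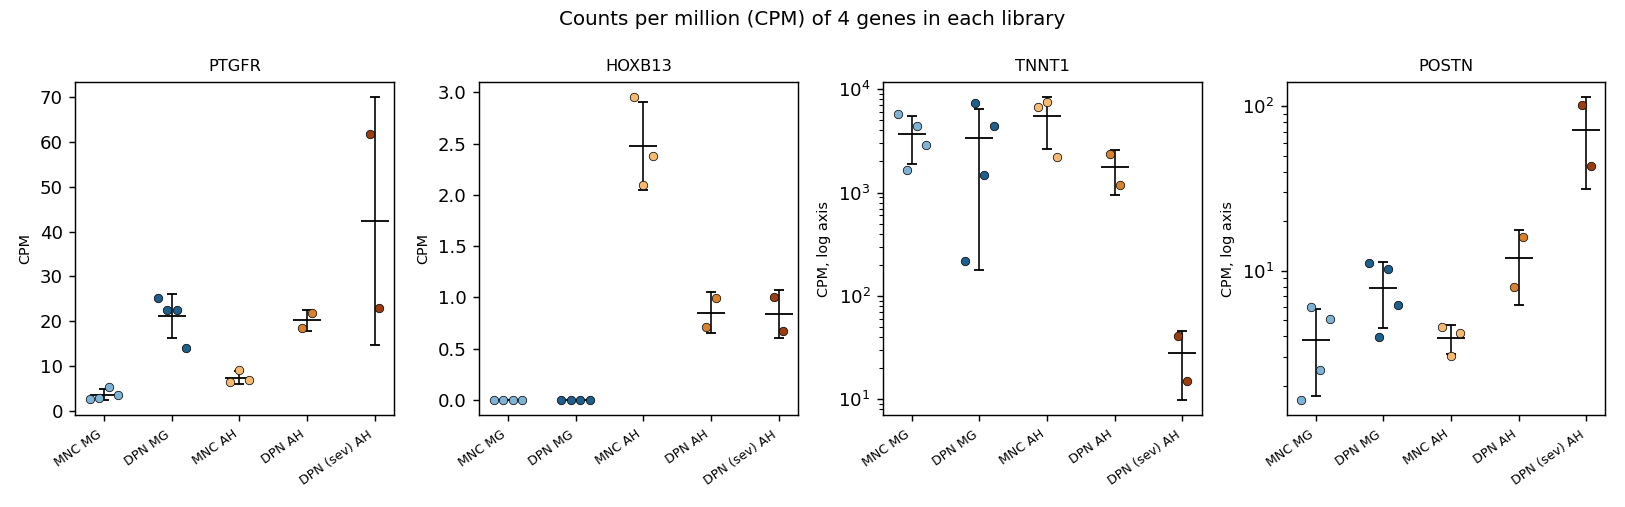
CPM of PTGFR, HOXB13, TNNT1 and POSTN (vertical, log axis for the last 2) in each library, grouped along the horizontal axis by diagnosis and muscle, with points for libraries and bars for the mean and SD of each group (n = 4, 4, 3, 2 and 2). HOXB13 had 0 counts in all 8 MG libraries, and TNNT1 averaged 27.9 CPM in DPN (sev) AH against 5480 in MNC AH.

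The second question was the same for foot muscle, with both neuropathy groups pooled (all DPN AH, n = 4, against MNC AH, n = 3). Here 674 genes passed, 242 higher and 432 lower, at edgeR QL adjusted p under the threshold. Among the higher, KCNJ16, an inward rectifier potassium channel (ENSG00000153822.13, chromosome 17, 70053429 to 70135608), rose 18.9-fold, from 0.493 ± 0.141 CPM (SD, n = 3) to 9.52 ± 4.52 CPM (SD, n = 4), with an adjusted p of 0.033. GRK3, which desensitizes G protein-coupled receptors (log2 fold 1.81 ± 0.28), ADGRL2, a latrophilin adhesion receptor (1.90 ± 0.32), and MGP, an inhibitor of calcification (2.28 ± 0.41), rose in every library, each with an adjusted p of 0.033. TPRG1 rose 17.7-fold (4.15 ± 0.76, adjusted p = 0.036). The lower side was led by FEM1A, a substrate receptor of a ubiquitin ligase abundant in muscle, which fell from 60.0 ± 15.5 CPM (SD, n = 3) to 10.6 ± 3.29 CPM (SD, n = 4), 5.66-fold, with an adjusted p of 0.033.

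Some genes of energy metabolism fell in pooled foot muscle. Of 37 nuclear-encoded oxidative phosphorylation genes 5 fell, 0 rose and 32 did not pass (35 fell when adjusted over the list alone). The median was -1.51 (camera adjusted p = 3.3e-20, and adjusted p = 0.32 with an estimated correlation), with UQCRFS1, the Rieske iron-sulfur subunit of complex III (-2.19 ± 0.47), and COX5A of complex IV (-2.22 ± 0.54) among those past the threshold. Glycolysis and glycogen genes had 3 of 20 lower, with the phosphorylase kinase subunit PHKA1 (-2.44 ± 0.52), and 17 when adjusted over the list alone (median -1.67, adjusted p = 5.7e-12, and adjusted p = 0.23 with an estimated correlation). Fatty acid oxidation genes had 3 of 27 lower (14 lower and 1 higher adjusted over the list alone), among them ACADS, a short-chain acyl-CoA dehydrogenase (-2.15 ± 0.42), and the lipid droplet protein PLIN2 (-1.89 ± 0.41). Their median was -1.33 (adjusted p = 4.5e-08, and adjusted p = 0.37 with an estimated correlation). Mitochondrially encoded genes had a median of -1.51 with 0 of 13 past the threshold genome-wide and 7 adjusted over the list alone (adjusted p = 2.7e-06, and adjusted p = 0.41 with an estimated correlation). Insulin signalling and glucose uptake lost 2 of 20, TBC1D1 (-1.95 ± 0.33), a regulator of glucose transporter traffic, and IRS2 (-1.49 ± 0.38), an insulin receptor substrate. The list had 8 lower adjusted over the list alone (median -0.81, adjusted p = 9.1e-05, and adjusted p = 0.23 with an estimated correlation).

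Some genes of muscle wasting and calcium handling fell as well. Atrophy ubiquitin ligases and autophagy had 3 of 25 lower and 22 not passing (11 lower and 1 higher adjusted over the list alone), at a median of -0.87 (camera adjusted p = 1.1e-05, and adjusted p = 0.23 with an estimated correlation). The 3 were TRIM63, the muscle ubiquitin ligase MuRF1 (-2.62 ± 0.46), the forkhead factor FOXO4 (-2.31 ± 0.38) and the lysosomal regulator TFEB (-1.57 ± 0.40). Calcium handling lost 3 of 23, the potassium channel subunit KCNJ11 (-2.50 ± 0.40), the junction protein JPH1 (-1.77 ± 0.37) and the sarcoplasmic calcium-binding protein HRC (-2.06 ± 0.51). Adjusted over the list alone, 8 were lower and 1 higher (median -1.13, adjusted p = 1.1e-06, and adjusted p = 0.32 with an estimated correlation). Slow fibre contractile proteins were lower as a list but with 0 of 14 members past the threshold, ATP2A2 at an adjusted p of 0.06, or 0.032 with the donor as a random block (median -2.45, adjusted p = 0.00013, and adjusted p = 0.48 with an estimated correlation). Satellite cell genes, with PAX7 at -1.59 ± 0.47 and an adjusted p of 0.058 (0.044 with the donor as a random block), had a median of -0.39 (adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). Immediate early and heat shock genes had a median of -0.90 (adjusted p = 0.024, and adjusted p = 0.63 with an estimated correlation). VEGFA (-2.40 ± 0.57) and the oxygen sensor EGLN1 (-2.11 ± 0.40) fell, both in the hypoxia list, and HOXC10 (-1.72 ± 0.43), a limb-patterning gene, fell too.

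A few matrix genes rose in pooled foot muscle. Collagens and matrix had 4 of 36 higher, 0 lower and 32 not passing (6 higher adjusted over the list alone). They were POSTN, periostin (3.42 ± 0.76), VCAN, versican (2.41 ± 0.56), ELN, elastin (2.14 ± 0.56), and LOX, which cross-links collagen (2.06 ± 0.44). The list median was 0.88 (camera adjusted p = 0.00023, and adjusted p = 0.59 with an estimated correlation). The chemokine CXCL14 rose (1.94 ± 0.51, adjusted p = 0.048). Macrophage genes (median 0.84, adjusted p = 0.0016) and fibroblast genes (0.73, 0.0089) were higher as lists, each with an adjusted p of 0.55 with an estimated correlation. All 6 mast cell genes were positive (median 1.35, adjusted p = 0.0056, and adjusted p = 0.32 with an estimated correlation), and 5 passed adjusted over the list alone. KIT, the stem cell factor receptor, had a genome-wide adjusted p of 0.077. Keratinocyte scores lay above MNC AH (-0.03 to 0.42) in all 4 DPN foot libraries (0.78 to 1.66). Camera did not call the list (median 1.08, adjusted p = 0.13) and fry did (0.035). The scores rest on PERP, DSP, KRT10 and SFN alone, which averaged 0.177 to 4.25 CPM in MNC AH. The listed KRT1, KRT5, KRT14 and LGALS7 were not among the genes tested.

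The count and some folds in pooled foot muscle depended on single libraries. Another split of the same foot libraries gave 1372 genes, so chance was not excluded as a source of the count. Without DPN (sev) AH replicate 1 the log2 folds of POSTN and VCAN were 2.57 (adjusted p = 0.13) and 1.44 (0.11). That of KCNJ11 was -1.83 without MNC AH replicate 3 (0.11), that of PHKA1 -1.74 without MNC AH replicate 2 (0.10) and that of VEGFA -3.20 without DPN AH replicate 1 (0.016). The count was 0 without DPN (sev) AH replicate 1, DPN (sev) AH replicate 2, MNC AH replicate 2 or MNC AH replicate 3, 298 without DPN AH replicate 2, 354 without MNC AH replicate 1 and 2160 without DPN AH replicate 1. Without scaling factors the split became 6765 higher and 135 lower against 242 and 432, as the median fold of all genes moved by 1.01 on the log2 scale. The medians of the atrophy, insulin, satellite cell and immediate early lists then became 0.10, 0.19, 0.58 and 0, so their sign rests on scaling. Of the 14 list calls 10 held in each of the 7 fits without 1 library. The collagen call was lost without MNC AH replicate 2 (adjusted p = 0.088) and the fibroblast call without DPN AH replicate 2 (0.056). The satellite cell call was lost without DPN (sev) AH replicate 2 (0.074) or MNC AH replicate 3 (0.082), and the immediate early call without DPN AH replicate 2 (0.053) or MNC AH replicate 3 (0.29).

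**Figure D3:**
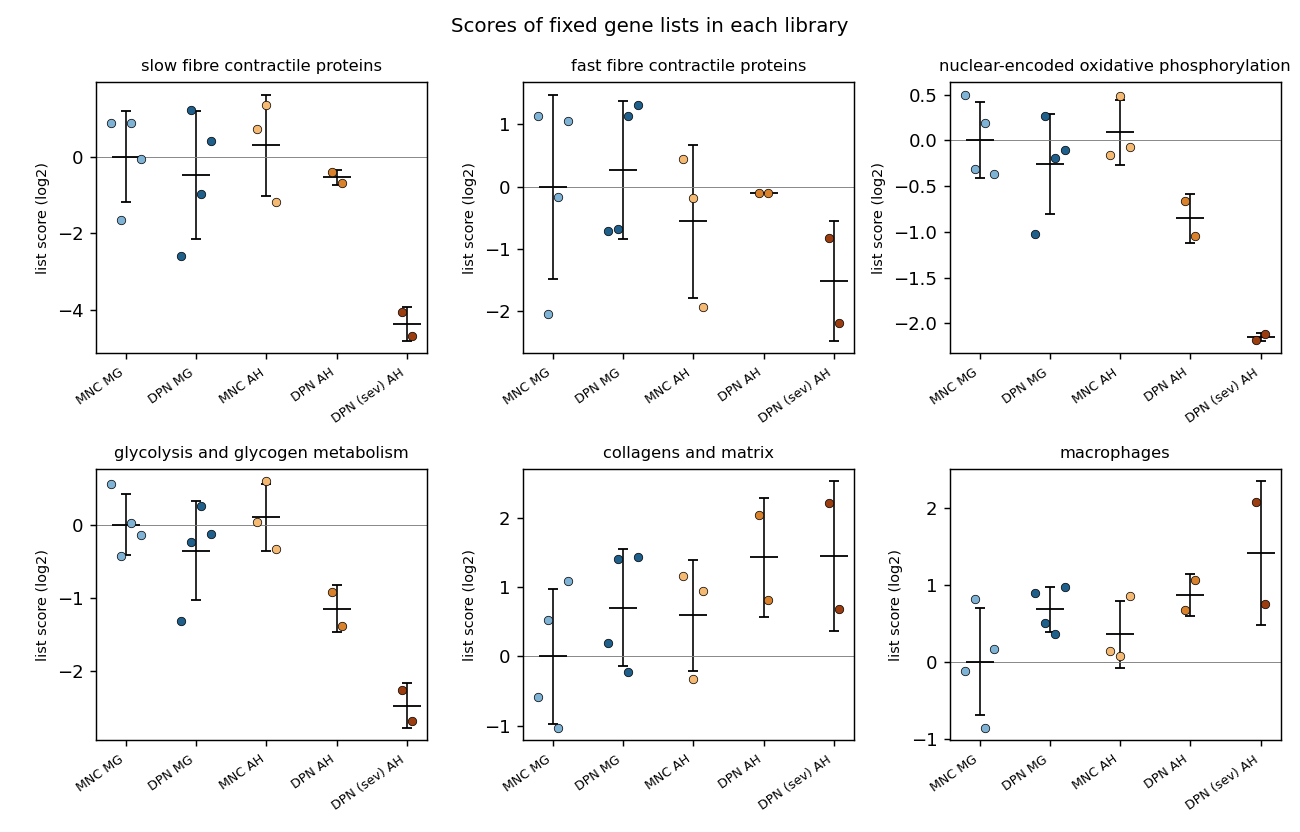
Score of 6 fixed gene lists (vertical, mean log2 CPM of the members relative to the mean of MNC MG) in each library, grouped along the horizontal axis, with points for libraries and bars for the mean and SD of each group (n = 4, 4, 3, 2 and 2). The slow fibre scores of the 2 DPN (sev) AH libraries, -4.06 and -4.68, were the lowest of all 15.

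The third question was how far the DPN (sev) AH libraries stood from control foot muscle (n = 2 against n = 3). It gave the largest count, 2540 genes, 950 higher and 1590 lower. Slow-twitch muscle RNAs fell furthest. TNNT1, slow skeletal troponin T (ENSG00000105048.16, chromosome 19, 55132794 to 55149354), fell 197-fold, from 5480 ± 2840 CPM (SD, n = 3) to 27.9 ± 18.0 CPM (SD, n = 2). Its log2 fold was -7.62 ± 1.41, with an edgeR QL adjusted p of 0.008. MYL2, the slow regulatory light chain (-7.80 ± 1.67, adjusted p = 0.012), TPM3, slow tropomyosin (-5.63 ± 1.20, adjusted p = 0.011), and ATP2A2, the calcium pump of slow fibres (-4.72 ± 0.99, adjusted p = 0.011), fell as well. Of the 14 slow fibre genes 10 fell, 0 rose and 4 did not pass (12 lower and 1 higher adjusted over the list alone), at a median of -5.61 (camera adjusted p = 8.8e-09, and adjusted p = 0.29 with an estimated correlation). Fast fibre genes had a median of -1.13 and did not pass as a list (adjusted p = 0.088). Of their 16 members 3 fell, the calcium buffer CASQ1 (-2.89 ± 0.76), the Z-disc protein MYOZ1 (-2.54 ± 0.68) and the light chain kinase MYLK2 (-5.03 ± 1.43).

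RNAs of energy metabolism were lower in the 2 DPN (sev) AH libraries. Oxidative phosphorylation had 32 of 37 genes lower and 5 not passing (36 lower adjusted over the list alone). COX5A led them and fell from 170 ± 65.2 CPM (SD, n = 3) to 13.7 ± 0.358 CPM (SD, n = 2), 12.4-fold, with UQCRFS1 (-3.11 ± 0.53) and the malate dehydrogenase MDH2 (-3.70 ± 0.64). Its median was -2.32 (camera adjusted p = 7.9e-27, and adjusted p = 0.19 with an estimated correlation). Of 13 mitochondrially encoded genes 9 fell, including MT-ATP6 (-2.66 ± 0.70) and MT-CO1 (-2.39 ± 0.66), and 12 adjusted over the list alone (median -2.34, adjusted p = 6.8e-08, and adjusted p = 0.32 with an estimated correlation). Glycolysis and glycogen genes had 14 of 20 lower (17 adjusted over the list alone), with PYGM, the muscle glycogen phosphorylase, down 36.2-fold (adjusted p = 0.0075) and the aldolase gene ALDOA down 12.9-fold. The list was lower as a whole (median -2.31, adjusted p = 5e-13, and adjusted p = 0.19 with an estimated correlation). Fatty acid oxidation lost 13 of 27 and gained 1 (17 lower and 1 higher adjusted over the list alone), with ACADS (-2.93 ± 0.48) and the mitochondrial carrier UCP3 (-3.80 ± 0.75) lower. The list was called as well (median -2.03, adjusted p = 2.7e-09, and adjusted p = 0.29 with an estimated correlation). The insulin-responsive glucose transporter SLC2A4 fell 14.3-fold (adjusted p = 0.014) and the kinase AKT2 2.80-fold (0.011). They were 2 of 5 lower in a list of 20, with 7 lower adjusted over the list alone (median -0.83, adjusted p = 0.00051, and adjusted p = 0.19 with an estimated correlation).

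Some atrophy, calcium handling and myogenic genes fell. TRIM63 fell from 139 ± 65.2 CPM (SD, n = 3) to 14.5 ± 5.27 CPM (SD, n = 2), 9.57-fold, and FOXO4 7.57-fold, while CBLB, another ubiquitin ligase of the same list, rose 3.48-fold (adjusted p = 0.013). The list had 8 lower, 1 higher and 16 not passing (14 lower and 2 higher adjusted over the list alone), at a median of -1.17 (camera adjusted p = 0.00013, and adjusted p = 0.19 with an estimated correlation). Calcium handling had 9 of 23 lower (16 lower and 2 higher adjusted over the list alone), with KCNJ11 (-3.01 ± 0.50), HRC (-3.09 ± 0.56) and the coupling adaptor STAC3 (-1.79 ± 0.38). The median was -1.75 (adjusted p = 2.8e-08, and adjusted p = 0.19 with an estimated correlation). Among satellite cell and myogenic genes, MYOD1, a master regulator of myogenesis (-2.03 ± 0.62, adjusted p = 0.054 with the donor as a random block), DES, desmin (-2.68 ± 0.62), and DLK1 (-6.29 ± 1.58) fell, 3 of 21 (median -0.70, adjusted p = 0.0061, and adjusted p = 0.21 with an estimated correlation). RAPSN, which anchors acetylcholine receptors at the neuromuscular junction, fell 3.24-fold (adjusted p = 0.013), in a list of 20 that was not called (median -0.82, adjusted p = 0.31). VEGFA fell 15-fold (adjusted p = 0.0044), EGLN1 5.95-fold, HOXC10 7.03-fold (0.0041), P2RY2, a nucleotide receptor, 28.6-fold (0.0041), and the ribosomal stalk gene RPLP1 4.15-fold (0.019).

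Some of the genes that rose belong to connective tissue and immune cells. AOX1, aldehyde oxidase 1 (ENSG00000138356.13, chromosome 2, 200585868 to 200677064), had the smallest adjusted p, 0.0035, and rose 10.9-fold, from 5.52 ± 1.04 CPM (SD, n = 3) to 60.3 ± 16.8 CPM (SD, n = 2). POSTN rose 18.4-fold, to 72.2 ± 41.1 CPM (SD, n = 2) from 3.91 ± 0.782 CPM (SD, n = 3), with an adjusted p of 0.0038. VCAN (2.95 ± 0.54), LOX (2.26 ± 0.49) and ELN (2.09 ± 0.64) rose with it, 4 of 36 matrix genes (5 adjusted over the list alone). The list had a median of 0.93 (camera adjusted p = 0.0026, and adjusted p = 0.74 with an estimated correlation). The fibroblast growth factor FGF7 rose 16.8-fold, the integrin ligand EDIL3 38.8-fold, IGF1 11.5-fold (adjusted p = 0.01), HGF 2.99-fold (0.046, and 0.086 with the donor as a random block), FSTL1 4.30-fold (0.027), the death receptor FAS 4.17-fold (0.031), PPARG 3.57-fold (0.011) and COMP 34.5-fold (0.019). Macrophage genes had 3 of 17 higher (5 adjusted over the list alone), MRC1 (1.68 ± 0.41, adjusted p = 0.054 with the donor as a random block), CD163 (1.76 ± 0.51) and the Fc receptor FCGR3A (2.81 ± 0.58). The median was 1.12 (adjusted p = 0.00051, and adjusted p = 0.51 with an estimated correlation). In the mast cell list 2 of 6 rose, HDC, which makes histamine (1.72 ± 0.51, adjusted p = 0.062 with the donor as a random block), among them, and 5 adjusted over the list alone (median 1.65, adjusted p = 0.016, and adjusted p = 0.30 with an estimated correlation). The interferon-stimulated genes IFI44L (1.59 ± 0.40) and XAF1 (1.23 ± 0.35) were the 2 of 20 that rose, 3 adjusted over the list alone (median 0.34, adjusted p = 0.036, and adjusted p = 0.56 with an estimated correlation). CXCL14 (2.13 ± 0.58) and the pentraxin PTX3 (3.79 ± 1.00) were the 2 of 22 cytokine, chemokine and complement genes (median 0.59, adjusted p = 0.022, and adjusted p = 0.56 with an estimated correlation). Red blood cell and neutrophil genes were higher (median 2.35, adjusted p = 0.031, and adjusted p = 0.64 with an estimated correlation). The neutrophil receptors CSF3R (2.36 ± 0.70) and CXCR2 (3.80 ± 1.09) passed, but CXCR2 did not with the donor as a random block (adjusted p = 0.24), and its log2 fold was -0.14 without DPN (sev) AH replicate 2. Several of these rises rested on DPN (sev) AH replicate 1, with 88.1 and 7.06 CPM of COMP in replicates 1 and 2, 102 and 11.1 CPM of IGF1 and 475 and 74.3 CPM of VCAN. Without it the log2 folds were 2.42 for COMP, 1.24 for IGF1, 1.13 for VCAN, 1.59 for LOX, 0.41 for FSTL1, 0.80 for HGF, 0.66 for MRC1, 1.57 for FCGR3A, 0.77 for HDC, 1.46 for CXCL14 and 2.47 for PTX3, none past the threshold (adjusted p from 0.15 to 0.70). It was 3.07 for FGF7 (0.058) and 3.52 for POSTN (0.041). Without replicate 2 it was 6.07 for COMP (0.02), 4.46 for IGF1 (0.0035), 3.83 for VCAN (0.0013), 4.08 for EDIL3 (0.017) and 1.00 for CSF3R (0.47). Without MNC AH replicate 3 it was 7 for COMP (0.023), 3.47 for CSF3R (0.02) and 2.37 for CD163 (0.024). CSF3R and EDIL3 moved the other way without DPN (sev) AH replicate 1, to log2 folds of 3.12 and 6.01. Keratinocyte scores were also higher, 1.58 and 1.66 in DPN (sev) AH against -0.03 to 0.42 in MNC AH. Of the 8 keratinocyte genes 4 were tested (PERP, DSP, KRT10 and SFN, without KRT1, KRT5, KRT14 or LGALS7) and 1 rose. Camera did not call the list (median 1.44, adjusted p = 0.11) while fry did (0.0055). A share of skin or other tissue in these libraries was not tested.

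The count was 54 without DPN (sev) AH replicate 1, 586 without DPN (sev) AH replicate 2, 1357 without MNC AH replicate 2 and 1558 without MNC AH replicate 3, and 909 when only the 5 libraries compared were fitted. Some lower genes moved too. Without DPN (sev) AH replicate 1 the log2 folds of TNNT1, TPM3, MYLK2 and SLC2A4 were -8.43, -6.28, -6.20 and -3.03 (adjusted p from 0.075 to 0.15), and that of P2RY2 was -5.75 (0.034). Without replicate 2 TNNT1 and MYLK2 were at -6.99 (0.062) and -4.28 (0.20), and SLC2A4 and P2RY2 at -5.38 (0.025) and -4.17 (0.021). Without MNC AH replicate 2 MYL2 and TPM3 were at -6.94 (0.028) and -4.90 (0.027), and without MNC AH replicate 3 KCNJ11 and RPLP1 at -2.31 (0.014) and -1.31 (0.059), and DLK1 at -5.66, still past the threshold. Of the 15 list calls 8 held in each of the 5 fits without 1 library, all of them lower lists (slow fibre, oxidative phosphorylation, mitochondrially encoded, glycolysis, fatty acid oxidation, insulin, atrophy and calcium). Without DPN (sev) AH replicate 1 the collagen (adjusted p = 0.73), macrophage (0.28), cytokine (0.26) and mast cell (0.24) calls were lost. Its collagen and macrophage scores were 2.21 and 2.07 against 0.68 and 0.75 in replicate 2, and MNC AH ranged from -0.32 to 1.16 and from 0.07 to 0.86. Without DPN (sev) AH replicate 2 the satellite cell (0.074), interferon-stimulated (0.084) and blood (0.88) calls were lost. Without MNC AH replicate 1 the blood (0.13) and mast cell (0.063) calls went, and without MNC AH replicate 2 the collagen (0.13), cytokine (0.17), interferon-stimulated (0.23) and blood (0.17) calls. AOX1, POSTN, EDIL3 and P2RY2 stayed past the threshold in every fit. Without scaling factors the split was 8798 higher and 308 lower against 950 and 1590 (median shift 1.26), and the medians of the atrophy, insulin and satellite cell lists became 0.03, 0.38 and 0.52.

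The fourth question was whether the other neuropathy group, DPN AH (n = 2), already differed from MNC AH (n = 3). With edgeR QL 0 genes passed, the smallest adjusted p being 0.43, while 2054 had an unadjusted p under 0.05, DESeq2 called 60, limma-voom 0 and edgeR QL without a filter 516. The genes with the strongest evidence were ones called in the pooled comparison, MGP (log2 fold 2.49 ± 0.46, adjusted p = 0.43), GRK3 (1.60 ± 0.31), FOXO4 (-1.88 ± 0.42), KCNJ11 (-2.13 ± 0.48), TRIM63 (-2.18 ± 0.53) and TBC1D1 (-1.83 ± 0.43), and none passed. Camera called 15 lists, 6 higher and 9 lower. All 37 oxidative phosphorylation genes were negative, UQCRFS1 at -1.63 ± 0.49 (median -0.98, camera adjusted p = 1.4e-14, and adjusted p = 0.32 with an estimated correlation). So were all 20 glycolysis genes (median -1.14, adjusted p = 2.8e-09, and adjusted p = 0.28 with an estimated correlation). Mitochondrially encoded (median -0.99, 0.00031), slow fibre (-1.49, 0.016) and immediate early genes (-0.92, 0.0076) were lower, each with an adjusted p of 0.53 with an estimated correlation. So were atrophy (-0.73, 1.1e-05) and insulin signalling genes (-0.60, 0.00012, IRS2 at -1.71 ± 0.48), both with an adjusted p of 0.25 with an estimated correlation. Fatty acid oxidation (-0.85, 1.1e-05, and adjusted p = 0.47 with an estimated correlation) and calcium handling (-0.75, 0.00015, and adjusted p = 0.32 with an estimated correlation) made up the rest. The higher lists included fibroblasts with LUM, lumican, at 1.92 ± 0.59 (median 0.95, 1.1e-05, and adjusted p = 0.34 with an estimated correlation). Mast cells (1.17, 0.0031, and adjusted p = 0.32 with an estimated correlation) and perineurial and tendon cells (1.19, 0.0079, and adjusted p = 0.39 with an estimated correlation) were among them too. Collagens and matrix with LOX at 1.82 ± 0.49 (0.86, 1.1e-05), adipocytes (0.92, 0.019) and macrophages (0.48, 0.016) were also higher, each with an adjusted p of 0.53 with an estimated correlation. Of the 15 calls 7 held in each of the 5 fits without 1 library (oxidative phosphorylation, glycolysis, fatty acid oxidation, atrophy, insulin, calcium and fibroblasts). The slow fibre call was lost without DPN AH replicate 1 (adjusted p = 0.057), DPN AH replicate 2 (0.055), MNC AH replicate 1 (0.067) or MNC AH replicate 2 (0.33), and the mitochondrially encoded call without MNC AH replicate 2 (0.18). The collagen and adipocyte calls were lost without DPN AH replicate 1 (0.29 each) or MNC AH replicate 2 (0.051 and 0.094). Macrophages were lost without DPN AH replicate 2 (0.27), MNC AH replicate 1 (0.12) or MNC AH replicate 2 (0.14), and perineurial genes without DPN AH replicate 2 (0.058) or MNC AH replicate 2 (0.18). Mast cells were lost without DPN AH replicate 2 (0.058), and immediate early genes without it (0.056) or MNC AH replicate 3 (0.18). The insulin median became 0.06 without scaling factors. Keratinocyte scores, 0.78 and 1.02, lay above those of MNC AH (-0.03 to 0.42), in a list that was not called (camera adjusted p = 0.23, fry 0.20). With 2 libraries a missed threshold does not show that genes did not differ.

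The fifth question compared the 2 neuropathy groups of foot muscle directly, DPN (sev) AH against DPN AH (n = 2 each). With edgeR QL 0 genes passed (smallest adjusted p 0.42), 1421 had an unadjusted p under 0.05, DESeq2 called 122, all lower, limma-voom 0 and edgeR QL without a filter 391. The fit with only these 4 libraries called 8, and the fit without DPN (sev) AH replicate 2 called 1. TNNT1 was 63.1-fold lower in DPN (sev) AH (27.9 ± 18.0 against 1760 ± 816 CPM, SD, n = 2 each) and MYL2 67.6-fold lower, both with an adjusted p of 0.53. AOX1 (2.16 ± 0.43) and POSTN (2.58 ± 0.62) were higher, while P2RY2 (-3.38 ± 0.66), MYOD1 (-2.88 ± 0.67), COX5A (-2.12 ± 0.53), PYGM (-3.55 ± 0.90) and the ubiquitin-conjugating UBE2QL1 (-3.02 ± 0.55) were lower, none past the threshold. Camera called 15 lists, 4 higher and 11 lower. Slow fibre genes had a median of -4.04 (camera adjusted p = 1.1e-17) with 12 of 14 lower adjusted over the list alone, and oxidative phosphorylation -1.39 (5.5e-26) with 22 of 37, both with an adjusted p of 0.16 with an estimated correlation. Fast fibre genes, CASQ1 at -1.93 ± 0.76 among them, had a median of -1.13 (adjusted p = 0.00075, and adjusted p = 0.57 with an estimated correlation). Glycolysis (-1.02, 1.1e-10) and calcium handling (-1.13, 1.9e-08) followed, both with an adjusted p of 0.16 with an estimated correlation, as did mitochondrially encoded (-1.32, 2.4e-08) and fatty acid oxidation genes (-1.18, 1.9e-08), both with an adjusted p of 0.46 with an estimated correlation. Neuromuscular junction genes (-0.64, 0.024, and adjusted p = 0.60 with an estimated correlation) and satellite cell genes (-0.25, 0.0045, and adjusted p = 0.23 with an estimated correlation) were lower as well. Ribosomal proteins (-0.28, 0.014) and fibroblasts (-0.47, 0.024) completed the lower lists, both with an adjusted p of 0.61 with an estimated correlation. Red blood cells and neutrophils with CSF3R at 2.26 ± 0.79 (median 2.41, 0.0035), cytokines (0.67, 0.0035) and interferon-stimulated genes (0.32, 0.019) were higher, each with an adjusted p of 0.57 with an estimated correlation. So were macrophages (0.57, 0.0028, and adjusted p = 0.60 with an estimated correlation).

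Of those 15 calls 6 held in each of the 4 fits without 1 library (slow fibre, oxidative phosphorylation, glycolysis, calcium, mitochondrially encoded and fatty acid oxidation). The blood call rested on DPN (sev) AH replicate 2, with scores of -0.74 and 2.77 against -0.42 and -0.24 in DPN AH, and without that library the direction turned (adjusted p = 0.83). The macrophage call rested on DPN (sev) AH replicate 1, with scores of 2.07 and 0.75 against 0.67 and 1.06, and turned without it (0.72). Without DPN (sev) AH replicate 1 the cytokine (0.23), neuromuscular junction (0.29) and ribosomal (0.071) calls were lost too. Without DPN (sev) AH replicate 2 so were the fibroblast (0.98), satellite cell (0.27), fast fibre (0.1) and interferon-stimulated (0.093) calls. Without DPN AH replicate 1 the neuromuscular junction (0.12) and macrophage (0.061) calls were lost, and without DPN AH replicate 2 the fibroblast (0.27), ribosomal (0.16) and interferon-stimulated (0.053) calls. Scaling mattered for the satellite cell, ribosomal and fibroblast lists, whose medians became 0.31, 0.28 and 0.10 without it, and the ribosomal list was not called (0.19).

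The sixth question was what sets foot muscle apart from calf muscle in controls (MNC AH, n = 3, against MNC MG, n = 4). HOXB13, a positional homeobox gene of the most posterior and distal tissues (ENSG00000159184.7, chromosome 17, 48724763 to 48729178), was the 1 gene past the threshold, with an edgeR QL adjusted p of 0.028. It averaged 2.48 ± 0.434 CPM (SD, n = 3) in MNC AH and had 0 counts in the 4 MNC MG libraries, at least 29-fold higher against a floor of 3 counts over those 4 libraries together. Other positional genes did not pass, with HOXA13 at 1.00 ± 0.39. Nor did the pharyngeal and craniofacial muscle factor TBX1 (88.3 ± 21.4 against 17.8 ± 10.1 CPM, SD, n = 3 and 4, adjusted p of 1) or the transcription factor TFCP2L1 (2.80 ± 0.62). The fast myosin gene MYH1 was 5.94-fold lower in foot muscle without passing (-2.57 ± 1.23). Camera called 5 lists, all higher in foot muscle and all with an adjusted p of 0.86 with an estimated correlation. They were collagens with LOXL1 (median 0.45, camera adjusted p = 2.6e-05), neuromuscular junction genes with NCAM1 (0.46, 0.012), embryonic contractile proteins with TNNT2 (0.89, 0.012), satellite cells with PAX7 (0.21, 0.019) and macrophages with CD163 (0.38, 0.029).

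At an unadjusted p under 0.05 there were 539 genes between the control muscles, 2.7 percent, again below the share that no difference would give. All 3 MNC AH donors also gave MNC MG libraries, with correlations of 0.43 to 0.47 between their muscles. The main fit ignored these pairs, which can lower that share, so it does not show that the muscles were alike. DESeq2 and limma-voom each called 1, and each of the 7 fits without 1 library called 0. With the donor as a fixed block 3 genes passed, all lower, HOXB13 not among them (adjusted p = 0.22), and 13 lists (10 higher and 3 lower) against 5. List counts without 1 library were 10 (MNC AH replicate 2), 11 (MNC MG replicate 2), 0 (MNC MG replicate 3) and 11 (MNC MG replicate 4), and 8 without scaling factors (7 higher and 1 lower). None of the 5 list calls held in each of the 7 fits. Those without MNC AH replicate 1 or 3, or MNC MG replicate 1 or 3, lost 4, 3, 4 and 5 of them, and the collagen call was lost without MNC AH replicate 1 (adjusted p = 0.13) or MNC MG replicate 3 (0.11).

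The seventh question was the same between the muscles of donors with neuropathy (all DPN AH, n = 4, against DPN MG, n = 4). With edgeR QL 0 genes passed (smallest adjusted p 0.12), 2773 had an unadjusted p under 0.05, and DESeq2 called 243 (13 higher and 230 lower). EdgeR QL without a filter called 12, limma-voom 1, and limma-voom with the donor as a random block 792 (271 higher and 521 lower). The fit without DPN MG replicate 1 called 1. ADGRL2 (1.60 ± 0.28), the mast cell tryptase TPSAB1, whose reads cannot be told from its paralog with certainty (1.91 ± 0.45), KIT (1.46 ± 0.40) and LOX (1.55 ± 0.38) were higher in foot muscle. ASB2, a muscle ubiquitin ligase adaptor (-2.12 ± 0.40), UQCRFS1 (-2.01 ± 0.44), ACADS (-1.85 ± 0.40), PAX7 (-1.74 ± 0.44), the calcium pump inhibitor SLN (-2.07 ± 0.53) and HOXC10 (-1.39 ± 0.40) were lower. Each of these 10 had an adjusted p of 0.24 in edgeR QL. All 10 passed in limma-voom with the donor as a random block (adjusted p from 0.017 to 0.032), and none passed in edgeR with the donor as a fixed block (0.11 to 0.15).

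Camera called 19 lists between the muscles of donors with neuropathy, 7 higher and 12 lower. Mast cell genes were the clearest of the higher (median 1.66, camera adjusted p = 1.3e-07, and adjusted p = 0.089 with an estimated correlation), all 6 past the threshold adjusted over the list alone. Collagens (0.76, 5.3e-06), fibroblasts (0.51, 0.0029), macrophages (0.66, 0.0034), red blood cells and neutrophils (1.82, 0.0099) and embryonic contractile proteins (0.63, 0.043) had an adjusted p of 0.46 with an estimated correlation. Perineurial and tendon cells (1.28, 0.0055) had an adjusted p of 0.27 with an estimated correlation. Of the lower lists, oxidative phosphorylation (-1.20, 7e-24), fatty acid oxidation (-1.23, 9.1e-14), glycolysis (-1.40, 1.6e-13), calcium handling (-0.84, 2e-07), insulin signalling (-0.60, 3e-05), atrophy (-0.44, 0.00045) and positional HOX genes (-0.58, 0.009) each had an adjusted p of 0.18 with an estimated correlation. Adjusted over the list alone, 26 of 37 oxidative phosphorylation genes, 14 of 27 fatty acid genes and 11 of 20 glycolysis genes were lower. Slow fibre genes (-1.65, 5.3e-05, and adjusted p = 0.43 with an estimated correlation) and satellite cells (-0.17, 0.0056, and adjusted p = 0.23 with an estimated correlation) were also lower. So were fast fibre (-1.17, 0.00038), mitochondrially encoded (-0.73, 0.00027) and immediate early genes (-1.16, 0.00038), each with an adjusted p of 0.46 with an estimated correlation. Of the 19 calls 14 held in each of the 8 fits without 1 library. The macrophage call was lost without DPN (sev) AH replicate 1 (adjusted p = 0.31), the satellite cell (0.062) and blood (0.35) calls without DPN (sev) AH replicate 2, and the immediate early call without DPN MG replicate 1 (0.32). The embryonic call was lost without DPN AH replicate 1 (0.12) or 2 (0.11), DPN (sev) AH replicate 1 (0.091), or DPN MG replicate 2 (0.059) or 3 (0.18). Without scaling factors the medians of the insulin, atrophy, positional HOX and satellite cell lists became 0.12, 0.11, 0.03 and 0.45, so their sign rests on scaling.

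The last question was whether the difference between diagnoses depended on the muscle. In the interaction test (edgeR QL, all 15 libraries) 0 genes passed, the smallest adjusted p being 0.62, with 1572 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. PAX7, the marker of satellite cells (-2.72 ± 0.64), ASB2 (-2.53 ± 0.57), ATP2A2 (-2.48 ± 1.11) and FEM1A (-2.40 ± 0.52) leaned to a more negative difference in foot muscle without passing. KCNJ16 (3.61 ± 0.93) and ADGRL2 (1.60 ± 0.42) leaned to a more positive one, also without passing. Camera called 11 lists in this test, 2 more positive and 9 more negative in foot muscle. Oxidative phosphorylation (median -1.33, camera adjusted p = 1.1e-17) and calcium handling (-1.09, 7.5e-07) had an adjusted p of 0.27 with an estimated correlation, and slow fibre genes (-2.14, 0.00014) one of 0.46. Glycolysis (-1.54, 1.6e-10), satellite cells (-0.83, 0.00016), atrophy (-0.61, 0.00023), insulin signalling (-0.58, 0.00033) and mast cells (1.36, 0.00041) each had an adjusted p of 0.22 with an estimated correlation. Fatty acid oxidation (-1.21, 8.9e-08, and adjusted p = 0.38 with an estimated correlation), immediate early genes (-0.56, 0.036, and adjusted p = 0.95 with an estimated correlation) and red blood cells and neutrophils (1.94, 0.00089, and adjusted p = 0.46 with an estimated correlation) completed the 11. In each of the 15 fits without 1 library 9 of the 11 calls held. The blood call was lost without MNC AH replicate 2 (adjusted p = 0.079). The immediate early call was lost in 6 fits, without DPN AH replicate 2 (0.073), DPN MG replicate 1 (0.88), MNC AH replicate 3 (0.38), or MNC MG replicate 1 (0.33), 3 (0.055) or 4 (0.17). With the donor as a fixed block 2 genes passed, 1 in each direction, and 17 lists (8 more positive and 9 more negative).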

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

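The tests of scaling factors, of a uniformly smaller muscle share and of the label of the foot library were chosen after the results were seen, as were the splits with all 15 libraries in the fit and the length and GC correction itself. The sequencing total of DPN MG replicate 2, 32066908 counts, stood apart from the other 3 DPN MG libraries (9582074 to 10746544). It was the 1 library far from its group among 74 tests of totals, mitochondrial share, scaling factors and list scores in the calf groups, and chance alone picks out about 1 in 20 such groups. Leaving it out gave 0 genes between DPN MG and MNC MG against 1.

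The difference between diagnoses was not the same in the 2 muscles for 11 lists by the camera test of the interaction at its preset correlation, and for 0 of the 11 with an estimated correlation. More negative in foot muscle were slow fibre genes (median difference of log2 folds -2.14), glycolysis (-1.54), oxidative phosphorylation (-1.33), fatty acid oxidation (-1.21), calcium handling (-1.09), satellite cells (-0.83), atrophy (-0.61), insulin signalling (-0.58) and immediate early genes (-0.56). More positive were red blood cells and neutrophils (1.94) and mast cells (1.36). The interaction test called 0 single genes. Without scaling factors the insulin median was 0.14 and the atrophy median -0.05, so the sign or size of those 2 rests on scaling.

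In DPN (sev) AH the contractile and energy-metabolism RNAs were far below MNC AH. Removing gene length and GC trends left the medians of the slow fibre, oxidative phosphorylation and glycolysis lists at -5.48, -2.31 and -2.18, from -5.56, -2.29 and -2.31, which argues against that bias as the whole cause. Without scaling factors they stayed at -4.26, -1.03 and -1.06, so the choice of factors did not make the decrease, although it set its size. A uniformly smaller share of muscle fibre RNA, as the only cause, would lower slow and fast genes alike. Yet the slow minus fast score was -3.22 and -2.48 in DPN (sev) AH against 0.28 to 1.55 in MNC AH. It was also low in the calf libraries of the same 2 donors, -2.09 and -1.87 (DPN MG replicates 3 and 1). The other DPN MG libraries were at 1.90 and -0.89. Low slow minus fast scores in these donors were therefore not confined to foot muscle. Of their calf libraries, only DPN MG replicate 1 had a slow fibre score, -2.58, below the MNC MG range (-1.66 to 0.87). DPN MG replicate 3 lay within that range at -0.96, with a fast fibre score of 1.13. A loss of slow fibres or a switch of fibre type, both with the severity the label may stand for, was not tested and remains open. Differences between 2 donors and 3 that have nothing to do with neuropathy remain open and were not tested either. A smaller muscle share together with a loss of slow fibres remains open too. The slow minus fast score was built from list scores already seen and cannot exclude it.

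The source name of DPN AH replicate 1 gives the other muscle. It held 7 HOXB13 counts, while all 8 MG libraries together held 0 and the other AH libraries 11 to 28, which argues against a calf sample under a foot label. Over 14 positional HOX and hindlimb genes it was also nearer to the other AH libraries (distance 0.62) than to MG (1.01), by a measure that placed 4 of 6 other AH and 7 of 8 MG libraries with their own muscle. The fit without it called 1 gene between muscles, HOXB13. A mixture of both muscles was not tested.

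DPN MG replicate 1 had the lowest slow fibre score of the calf libraries, -2.58 against -1.66 for the next one, MNC MG replicate 2. The next DPN MG library, replicate 3, was at -0.96. The tests for libraries far from their group did not pick out replicate 1 on this score. DPN MG replicates 1 and 3 come from the donors of DPN (sev) AH replicates 2 and 1. After removal of length and GC trends the gap of replicate 1 to the lowest of the other 3 DPN MG libraries was 1.59 against 1.62, which argues against that bias. The muscle of the donor of replicate 1, whether through neuropathy or otherwise, and tissue sampling remain open, since the 1 donor cannot separate them.

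Other splits of the same libraries, each fitted without the rest, decided nothing. The real splits gave 0 genes in all 4 comparisons, a count that 35 of 35 splits reach by definition. The highest count of any other split was 146 for DPN MG against MNC MG, 9 for pooled foot muscle, 418 between control muscles and 842 between the muscles of donors with neuropathy. The last set both DPN (sev) AH libraries with DPN MG replicate 1 and DPN AH replicate 2 against the rest. It kept the 2 libraries of a donor together for 2 of the 3 paired donors, 1 donor on each side, and these fits ignore the donor pairs. Limma-voom with all 15 libraries and the donor as a random block gave 792 for the real split. The other splits were not run in that way, so 792 cannot be set against 842. With all 15 libraries in the fit, 2 of 35 splits of the foot libraries gave at least the 674 genes of the real one, itself included. The other, with 1372 genes, put DPN AH replicate 1 with the 3 controls. The splits therefore do not exclude chance as a source of the 674.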

How the results depend on the processing

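Over 2074 alternative values of 153 gene results, 1651 kept their side of the threshold, 349 fell below it and 73 rose past it. Direction was compared only where the main or the alternative value passed. Changes of sign between values that both missed the threshold were therefore not counted. Counted in that way 1 reversed, CXCR2 in DPN (sev) AH against MNC AH (-0.14 without DPN (sev) AH replicate 2, up to 6.16 without MNC AH replicate 3). Most of these genes were chosen by a small p, which itself favours a stable direction. The causes of moved counts were not tested unless stated. Library totals without scaling factors and list counts without a library or with a fixed donor block were added after the data had been seen.

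For genes past the threshold, DESeq2 gave 8 for DPN MG against MNC MG, 2487 for pooled foot muscle, 60 for DPN AH against MNC AH, 122 for DPN (sev) AH against DPN AH and 243 between the muscles of donors with neuropathy, where the main counts were 1, 674, 0, 0 and 0. A fit with only the libraries compared has fewer libraries to estimate the spread and gave 0 for calf muscle, 0 for pooled foot muscle, 909 for DPN (sev) AH against MNC AH, 8 for DPN (sev) AH against DPN AH and 0 between control muscles. Limma-voom gave 0 for calf muscle, 313 for pooled foot muscle and 1 between the muscles of donors with neuropathy, and with the donor as a random block 0, 1223 and 792. No filter gave 273 for calf muscle, 516 for DPN AH, 391 for DPN (sev) AH against DPN AH and 12 between the muscles of donors with neuropathy. Without scaling factors the counts were 6900 for pooled foot muscle, 9106 for DPN (sev) AH against MNC AH and 0 between control muscles, by construction through the shift of all folds in the first 2. The fixed donor block gave 3 between control muscles and 2 for the interaction. DESeq2 size factors in edgeR moved no count by more than 1.5 times. The random block also ended the calls of PTGFR in calf muscle (adjusted p = 0.085) and, in DPN (sev) AH against MNC AH, of MYOD1 (0.054), MRC1 (0.054), HDC (0.062), HGF (0.086) and CXCR2 (0.24). It added ATP2A2 (0.032) and PAX7 (0.044) in pooled foot muscle and the 10 genes named between the muscles of donors with neuropathy. Limma-voom without the block also missed PTGFR (0.06), HDC (0.06), HGF (0.067) and CXCR2 (0.22). The fixed block ended HOXB13 (0.22).

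For lists, camera with an estimated correlation gave 0 in all 8 comparisons. Fry gave 10 for pooled foot muscle and 11 for DPN (sev) AH against MNC AH (main 14 and 15), 0 for calf muscle, DPN AH, DPN (sev) AH against DPN AH, control muscles and the interaction, and 9 between the muscles of donors with neuropathy against 19. The fixed donor block gave 13 between control muscles against 5 and 17 for the interaction against 11, and no scaling factors 8 between control muscles.

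Leaving out 1 library at a time gave ranges of 0 to 1 genes for calf muscle, 0 to 2160 for pooled foot muscle, 54 to 2062 for DPN (sev) AH, 0 to 0 for DPN AH, 0 to 1 for DPN (sev) AH against DPN AH, 0 to 0 between control muscles, 0 to 1 between the muscles of donors with neuropathy and 0 to 0 for the interaction. List ranges were 11 to 16, 13 to 18, 12 to 16, 10 to 18, 13 to 16, 0 to 11, 18 to 23 and 10 to 13 in the same order.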

Other observations

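PTGFR was looked at across both muscles after its values were seen. In foot muscle it averaged 20.2 ± 2.30 CPM (SD, n = 2) in DPN AH, 42.4 ± 27.5 CPM (SD, n = 2) in DPN (sev) AH and 7.5 ± 1.5 CPM (SD, n = 3) in MNC AH, with a log2 fold of 2.06 ± 0.41 in pooled foot muscle and an edgeR QL adjusted p of 0.042. The 8 DPN libraries ranged from 14.0 to 61.8 CPM and the 7 MNC libraries from 2.74 to 9.22, without overlap. Taking the mean log2 CPM per donor, 5 donors with neuropathy lay 2.26 above 4 controls (two-sided exact permutation p = 0.00794, the smallest the 126 arrangements allow), a p that does not account for the gene having been picked from 20060. Leaving out DPN (sev) AH replicate 1 or 2, or MNC AH replicate 1, 2 or 3, put the foot muscle adjusted p between 0.051 and 0.11.

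HOXB13 had counts only in foot muscle in donors with neuropathy as well, at a lower level than in controls. Counts were 28, 18 and 24 in MNC AH, 7 and 15 in DPN AH, and 15 and 11 in DPN (sev) AH, against 0 in every MG library. In DPN the AH mean was 0.844 ± 0.179 CPM (SD, n = 4), against 2.48 ± 0.434 CPM (SD, n = 3) in MNC AH. It was at least 16-fold above a floor of 3 counts over the 4 DPN MG libraries together. A mean under 1 CPM carries little information, and edgeR QL called 0 genes between the muscles of donors with neuropathy, HOXB13 included. For the 6 donors with both muscles the difference in counts averaged 17.17 (two-sided exact sign-flip p = 0.0312, the smallest 6 pairs allow). That p does not account for the gene having been picked from 20060, and 3 of the 6 pairs are control donors whose libraries were used to pick it.

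Some fixed lists were called in no comparison. In DPN (sev) AH against MNC AH the medians were 0.35 for growth factor, BMP and myostatin signalling, -0.35 for hypoxia and angiogenesis, 0.12 for p53 and senescence, 0.06 for proliferation, 0.22 for B and plasma cells, -0.29 for endothelial cells, 0.39 for pericytes and smooth muscle, -0.64 for Schwann cells and nerve and 1.44 for keratinocytes, with camera adjusted p from 0.11 to 0.93. Red blood cell and neutrophil scores were uneven within groups, 2.77 in DPN (sev) AH replicate 2 and -0.74 in replicate 1, with 1.73 in MNC AH replicate 3 and 1.5 in MNC MG replicate 2. Immediate early scores were 1.60 in DPN MG replicate 1, 1.93 in MNC MG replicate 2 and 0.80 in MNC AH replicate 3.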
